A study of Mus musculus with 14 samples.

How the data were processed

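RNA from 14 cultures of the mouse lens epithelial line αTN4-1 was measured, 1 control and 1 TGFβ culture of each of 7 stable lines. Per the labels' protocols, cells grew in medium with serum under neomycin selection, and treated cells received TGFβ in medium without serum. Libraries were made with a dual-mode mRNA kit and sequenced on a DNBSEQ-T7 instrument. Lines and treatments were taken from the sample titles. The growth protocol names neither of the 2 lines labelled with K, which the titles do. The strandedness of the libraries and the gene annotation release are not given in the sources used here.

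The submitters' processing notes name the genome build GRCm39, STAR 2.7.6a, StringTie 2.0.4 and edgeR, with no roles. The deposited tables have the column layout of StringTie gene abundances, with 40,853 gene identifiers each. They hold TPM as deposited by the authors, which sums to 1,000,000 in each library, FPKM as deposited by the authors, and the per-base coverage of each gene, per the file headers. Values that share a gene identifier (2 to 12 lines of a file) were summed. Between 19,322 and 22,145 genes per library are listed at 0, which can be a failed estimate as well as an absent transcript. The tables hold no read counts, so no count model was used and no counting interval is given. Sequencing depth was judged from the most frequent ratio of coverage to FPKM within a library. Mitochondrially encoded genes held 5.59% to 10.8% of TPM and the top 10 genes 8.11% to 13.4%. No libraries were duplicates of each other. Coordinates are those of the deposited tables, on GRCm39. A mouse annotation of another build was used for gene types alone.

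TPM was taken as log2(TPM + 1), and 12,927 genes with a mean of at least 1 TPM over the 14 libraries were tested. Fold changes are on this scale, which understates the change of low genes. The effect of TGFβ was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance and the line as a block, so that the 7 differences within lines are the replicates. The effects of S133A, K and R314A were fitted on the means of the 2 libraries of each of the 6 CREB lines, and their interactions with TGFβ on the differences, in a model with the S133 state and the zipper state. A line label pairs its control and TGFβ libraries. As a check, the deviations of the 2 libraries of a line from the treatment means correlated across genes with r of 0.614 to 0.845, against 0.275 or less with any library of another line. Adjusted p-values are by the Benjamini-Hochberg method, with a threshold of 0.05, and all p-values are two-sided. Single lines and the differences from Vector have 1 library per side, so only values, counts past 2-fold at a mean of at least 5 TPM, and percentiles of list medians among 10,000 random lists matched on mean expression are given.

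Before the data were examined, 34 gene lists, the designs and most alternatives were fixed. Lists with at least 5 tested genes (29) were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of each effect, and again with an estimated correlation. The test with an estimated correlation uses the residual degrees of freedom of the fit, which are few here, and its power was not measured. Some genes stand in several lists. Creb1 was named first. For TGFβ the rule named the 10 highest and 10 lowest changes among genes with an adjusted p under 0.05, a mean of at least 5 TPM and one direction in all lines. For S133A it named the same numbers, and 5 and 5 for K, R314A and the interactions. Where fewer than 3 genes in a direction passed, as in all of these, the 5 largest differences at a mean of at least 5 TPM and of one direction in all matched pairs were named instead. Against Vector the 3 highest and 3 lowest were named, and in each list up to 4 members with the smallest p. Predicted genes and pseudogenes were passed over.

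The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, FPKM, no intensity trend, leaving out each line in turn, a fit without the block, an exact Wilcoxon signed-rank test, control or TGFβ libraries alone, and all 12 libraries of the CREB lines with the line as a random block (statmod 1.5.0). After the data were seen, TPM rescaled without mitochondrially encoded genes, the 3 lines whose Creb1 was not below Vector, and list tests under the other pseudocounts, filters, scalings and trend and without each line were added. Lists were not tested without the block. The set of translation factors compared with ribosomal protein genes was narrowed, after its values were seen, to elongation and initiation factors and Pabpc1. Tested on simulated data with the 12,927 genes, the TGFβ fit recovered 83.0% of genes changed 1.5-fold, 94.2% changed 2-fold and 100% changed 4-fold. The S133A fit recovered 0%, 0% and 42.6%, and the fit of the S133A by TGFβ interaction 1.54%, 49.3% and 85.5%. False calls among unchanged genes numbered 16 for TGFβ, 1 for S133A and 6 for the interaction. Far fewer genes were changed in the simulation than were called for TGFβ in the data, so its rates need not hold there. The S133A fit thus recovers no differences of 2-fold or less, and the K and R314A fits, with fewer lines per group, were not simulated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.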

Results

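Gene expression was measured by RNA sequencing in αTN4-1, an epithelial line from the lens of transgenic mice whose lens cells were transformed by a viral T antigen. There were 7 stable lines. Besides the line labelled Vector, 3 were labelled for a CREB construct without S133A (KCREB, R314A-CREB and WT-CREB) and 3 for the same constructs with S133A added (S133A/R314A-CREB, S133A-KCREB and S133A-CREB). CREB is a transcription factor that binds cAMP response elements in DNA. S133A removes the serine that protein kinase A phosphorylates, R314A lies in the basic leucine zipper and is known to prevent binding of the CRTC coactivators, and KCREB is a mutant that no longer binds DNA and acts as a dominant negative. Each line gave 1 control library and 1 library treated with 20 ng/mL TGFβ for 24 h in medium without serum, which makes 14 libraries with no replicate of any line and treatment. The labels do not say whether the control cells were also kept without serum, so TGFβ and serum withdrawal cannot be separated. Between 12,545 and 13,081 genes per library reached 1 TPM. Read totals were not given. The per-base coverage that corresponds to 1 FPKM, which follows sequencing depth, ran from 5.05 in the control library labelled R314A-CREB to 10.1 in the TGFβ library labelled S133A-CREB, with a median of 6.70. Because the lines serve as the replicates, the p-values of single genes below describe the spread between lines, not between repeat cultures of 1 line. A list p-value at the preset correlation compares the genes of a list with the other genes tested. It thus reflects the spread between genes and not between lines.

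Creb1, the gene of the expressed protein (chromosome 1, 64571963 to 64643707, GRCm39), was examined first. In the Vector libraries it stood at 20.8 TPM in control and 23.1 TPM with TGFβ. It lay above these values in the lines labelled KCREB, with 25.8 and 30.1 TPM, and S133A-KCREB, with 34.0 and 38.3 TPM. It lay below them in the other 4 lines labelled for a CREB construct. The line labelled WT-CREB had 11.6 and 9.68 TPM, which is 0.555 and 0.419 times Vector. The line labelled R314A-CREB had 9.04 and 5.89 TPM, the line labelled S133A/R314A-CREB had 7.92 and 6.01 TPM, and the line labelled S133A-CREB had the lowest values, 6.59 and 4.43 TPM. Creb1 thus goes against the labels of 4 lines said to overexpress CREB, and lines are named below only as labelled. The labels do not give the species of the construct, and reads of a construct from another species need not be counted under mouse Creb1. The lines labelled with K had higher Creb1 than those labelled WT-CREB and S133A-CREB by 1.92 ± 0.34 (log2, SE), but this did not pass in limma over all genes (adjusted p = 0.275). Crem and Atf1, the other 2 members of the CREB subfamily, averaged 8.65 ± 2.69 and 77.3 ± 13.0 TPM in the control libraries and 13.5 ± 5.60 and 85.7 ± 11.3 TPM with TGFβ (mean ± SD, n = 7).

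**Figure D1:**
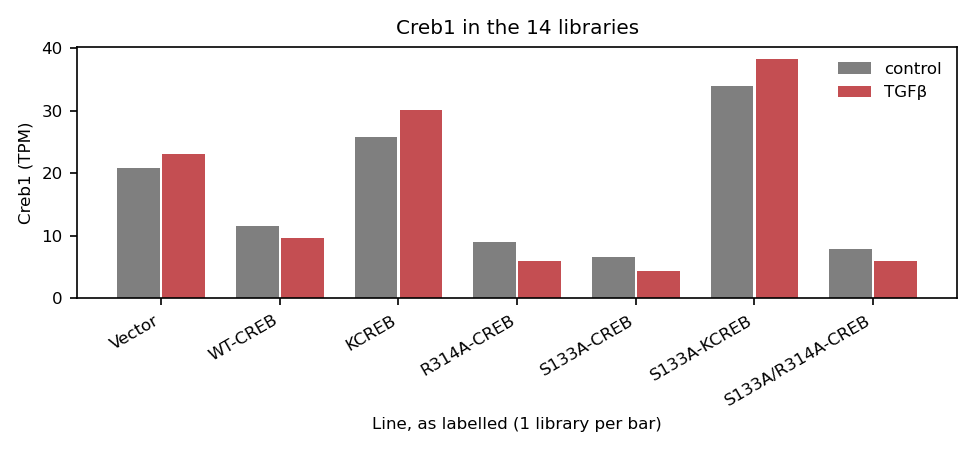
Creb1 in TPM (vertical axis) in the control and TGFβ library of each of the 7 lines as labelled, 1 library per bar. Creb1 lies between 4.43 and 11.6 TPM in the lines labelled WT-CREB, R314A-CREB, S133A-CREB and S133A/R314A-CREB, below both Vector bars at 20.8 and 23.1 TPM.

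The first comparison was TGFβ-treated against control cells across the 7 lines. Of 12,927 genes tested, 3110 rose and 2762 fell (limma with the line as a block, adjusted p under 0.05), and 134 rose and 207 fell by at least 2-fold. The balance between the directions turned with median-of-ratios scaling (2821 rose and 2984 fell) and with TPM rescaled without mitochondrially encoded genes (2851 and 2930). In all, 4441 genes (34.4%) differed in one direction in all 7 lines, where chance gives 1.56%. Ctsw, which encodes a cysteine protease of the cathepsin family (chromosome 19, 5515071 to 5518558), rose most among the named genes, from 15.5 ± 13.6 to 133.2 ± 68.0 TPM (mean ± SD, n = 7), a log2 change of 3.43 ± 0.33 (SE, 95% CI 2.68 to 4.18, adjusted p = 1.78e-04). Clu, the secreted chaperone clusterin (chromosome 14, 66205932 to 66218997), rose by 3.19 ± 0.56, although 1 library, the TGFβ library labelled S133A/R314A-CREB, held 261 TPM against 2.78 to 14.5 TPM in the other 6 TGFβ libraries. Acsbg1, a long-chain acyl-CoA synthetase, rose by 3.04 ± 0.36, the serine protease gene Prss46 by 2.86 ± 0.19 and the serotonin receptor gene Htr2b by 2.72 ± 0.22. The gelatinase Mmp9 rose by 2.55 ± 0.41, the matrix protein Tgfbi by 2.51 ± 0.44, Asb5 by 2.32 ± 0.36, the cytokine Lif by 2.28 ± 0.31 and Adgra1 by 2.22 ± 0.21.

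Among the genes that fell most, Aldh1a1, which makes retinoic acid from retinaldehyde (chromosome 19, 20469947 to 20620827), had a log2 change of -3.26 ± 0.22 (SE, 95% CI -3.74 to -2.77, adjusted p = 4.54e-05), from 279 ± 294 to 29.2 ± 31.3 TPM. Its neighbour Aldh1a7 changed by -2.30 ± 0.28, and the aldo-keto reductases Akr1c14 and Akr1c18 by -2.95 ± 0.17 and -2.86 ± 0.24. Members of these families share sequence, so the division of reads between copies, and with it these values, is uncertain. The small leucine-rich proteoglycans Prelp and Ogn changed by -2.73 ± 0.27 and -2.24 ± 0.35 and the matrix glycoprotein Efemp1 by -2.32 ± 0.36. Slurp1 had the lowest value, -3.44 ± 0.50, from 32.2 ± 45.1 to 0.648 ± 1.07 TPM. Ecrg4 (-2.77 ± 0.30) and Aspa (-2.61 ± 0.19) complete the 20 genes, whose adjusted p-values ran from 2.8e-05 for Akr1c14 to 0.00198 for Tgfbi. Without the line as a block, 1164 genes passed, and Asb5 (adjusted p = 0.213) and Efemp1 (0.281) did not.

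**Figure D2:**
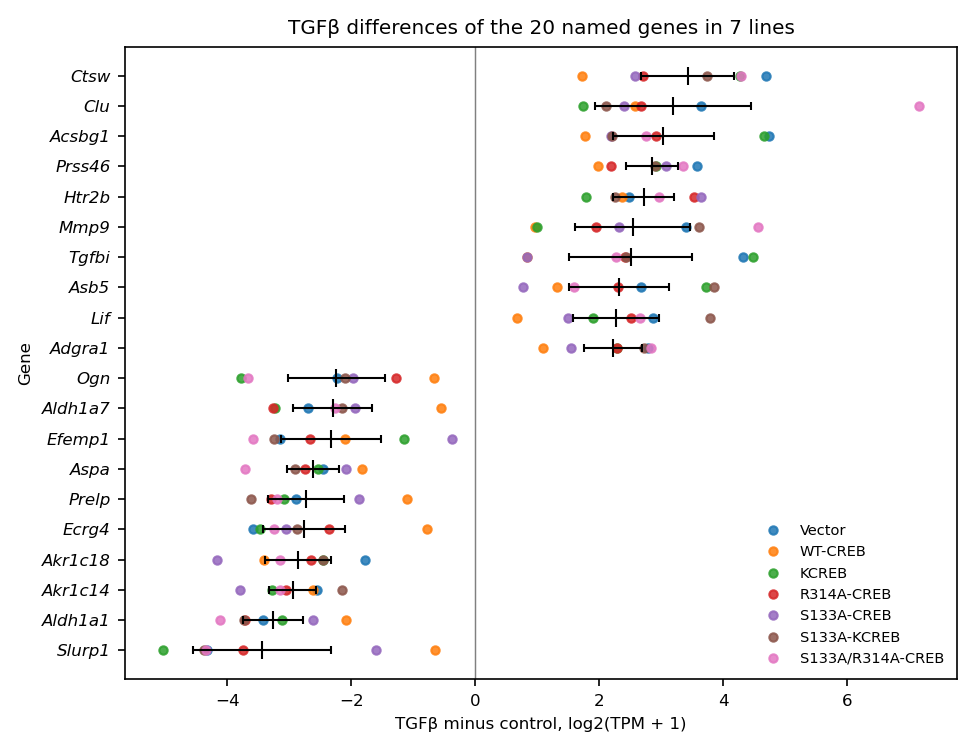
TGFβ minus control difference in log2(TPM + 1) (horizontal axis) of the 20 named genes (vertical axis). Points are the 7 lines, 1 control and 1 TGFβ library each, and black bars are the limma estimate with its 95% confidence interval. The line labelled S133A/R314A-CREB stands at 7.17 for Clu, against 1.74 to 3.65 in the other lines.

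Gene lists fixed beforehand were tested with camera in limma at a preset correlation of 0.01, and 11 of 29 lists passed. None of the 11 passed with an estimated correlation, and each such p is given beside its list. That test rests on few residual degrees of freedom and on the correlation estimated between genes, and its power was not measured. A list that failed it is thus not upheld by it, nor shown to be without a difference. SMAD targets induced by TGFβ ranked higher (adjusted p = 3.26e-05; adjusted p = 0.561 with an estimated correlation). Of 21 tested, 14 rose and 1 fell, or 15 and 1 adjusted over the list alone. Ccn2 rose from 168 ± 90.8 to 743 ± 238 TPM (log2 2.20 ± 0.24), Spsb1 by 1.20 ± 0.12, the inhibitory SMAD gene Smad7 by 0.93 ± 0.09 and Tgfb2 by 0.84 ± 0.07. The ATF4 and integrated stress response list ranked higher (adjusted p = 7.41e-04; adjusted p = 0.561 with an estimated correlation), with 17 of 24 members up and 3 down, both over all genes and adjusted over the list alone. Among them Cth rose by 0.90 ± 0.07, the serine hydroxymethyltransferase gene Shmt2 by 0.70 ± 0.07 and Atf4 by 0.39 ± 0.05. The unfolded protein response of the endoplasmic reticulum also ranked higher (adjusted p = 2.13e-05; adjusted p = 0.561 with an estimated correlation). In it 16 of 21 members rose and none fell, also adjusted over the list alone, including Xbp1 (0.93 ± 0.11), the chaperone Hspa5 (0.68 ± 0.10) and Sec61b (0.40 ± 0.04).

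Ribosome biogenesis genes ranked higher (adjusted p = 7.66e-09; adjusted p = 0.561 with an estimated correlation), and 24 of 28 rose with none down, or 26 adjusted over the list alone. Nop56 rose by 0.80 ± 0.10 and Nhp2 by 0.63 ± 0.07. The members Rrp1b, Rrp9 and Rrp12 were low throughout, with means of 1.17, 1.71 and 1.59 TPM over the 14 libraries. Cytosolic ribosomal protein genes ranked higher too (adjusted p = 7.66e-09; adjusted p = 0.561 with an estimated correlation), with 36 of 39 up and none down in either count and a median of 0.41. Rps14 went from 10.7 ± 2.51 to 15 ± 3.16 TPM and Rps23 from 13.0 ± 2.48 to 19.6 ± 2.58 TPM. These levels are low for the family in all libraries. The 82 cytosolic ribosomal protein genes had a median of 16.0 TPM over the 14 libraries, against 417 TPM for 21 translation factors. The list values of this family, here and for S133A and K below, thus describe deposited levels that are low throughout, and they need not follow the mRNAs in the cells. NF-kB and inflammatory genes ranked higher (adjusted p = 0.0414; adjusted p = 0.561 with an estimated correlation), with 8 of 15 up and 1 down in either count. Il6 rose by 1.77 ± 0.32 and the inhibitor gene Nfkbia by 0.60 ± 0.11, whereas the adhesion receptor gene Vcam1 fell, from 70.2 ± 70.6 to 17.9 ± 24.9 TPM (log2 -2.18 ± 0.12). This call was lost without the line labelled KCREB (adjusted p = 0.0624), R314A-CREB (0.0551) or S133A/R314A-CREB (0.0859).

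**Figure D3:**
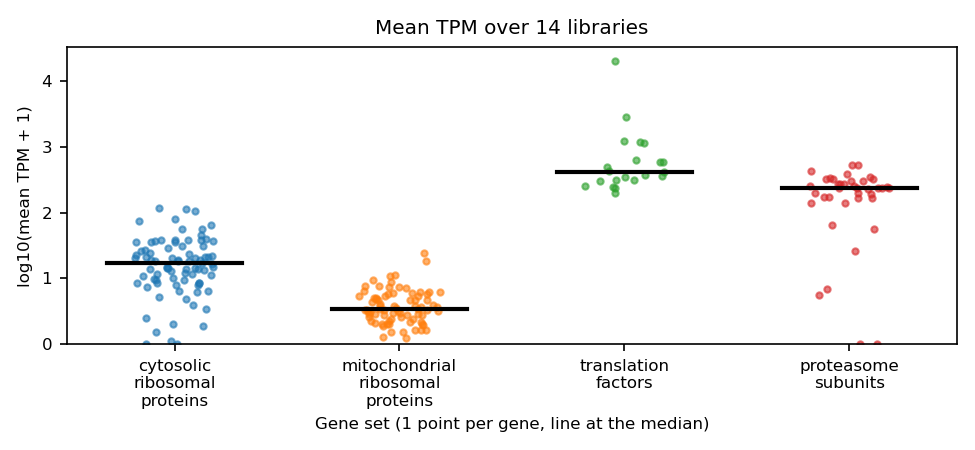
Mean TPM over the 14 libraries, as log10(mean TPM + 1), for 4 sets of genes, 1 point per gene with a line at the median. The 82 cytosolic ribosomal protein genes have a median of 16.0 TPM and the 78 mitochondrial ones 2.47 TPM, against 417 TPM for 21 translation factors and 234 TPM for 39 proteasome subunits.

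Among lists that ranked lower, cholesterol synthesis had 21 of 24 members down and none up, or 23 down adjusted over the list alone (adjusted p = 1.98e-07; adjusted p = 0.561 with an estimated correlation). Mvk changed by -0.91 ± 0.11, Lss by -0.88 ± 0.13 and Sqle, an early oxygenase of the pathway, by -0.60 ± 0.09. Lens fiber genes ranked lower (adjusted p = 0.00268; adjusted p = 0.561 with an estimated correlation), and 7 of 9 fell in either count, including Lctl (-1.39 ± 0.27) and the regulators Prox1 (-0.73 ± 0.16) and Hsf4. Lens capsule and basement membrane genes ranked lower (adjusted p = 0.00523; adjusted p = 0.561 with an estimated correlation), with 9 of 16 down and 1 up in either count, including Nid1 (-1.36 ± 0.17), Col4a6 (-0.99 ± 0.10) and Lamb2 (-0.57 ± 0.06). NRF2 antioxidant genes ranked lower (adjusted p = 0.00268; adjusted p = 0.592 with an estimated correlation), with 9 of 23 down and 1 up in either count, among them the glutathione transferase Gstm1 (-1.49 ± 0.19) and transketolase Tkt (-1.26 ± 0.18). Interferon response genes ranked lower (adjusted p = 0.0293; adjusted p = 0.670 with an estimated correlation), with 7 of 30 down and none up in either count, including Psmb9 (-0.80 ± 0.10) and Oas2 (-0.90 ± 0.18). The lines did not share this. The median of the interferon list was 0.73 in the line labelled R314A-CREB and 0.37 in the line labelled S133A-CREB, and between -0.83 and -0.43 in the other 5 lines. The call was lost with a pseudocount of 5 (adjusted p = 0.0539), in FPKM (0.0521), and without the line labelled WT-CREB (0.0975), KCREB (0.145) or S133A-KCREB (0.114).

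**Figure D4:**
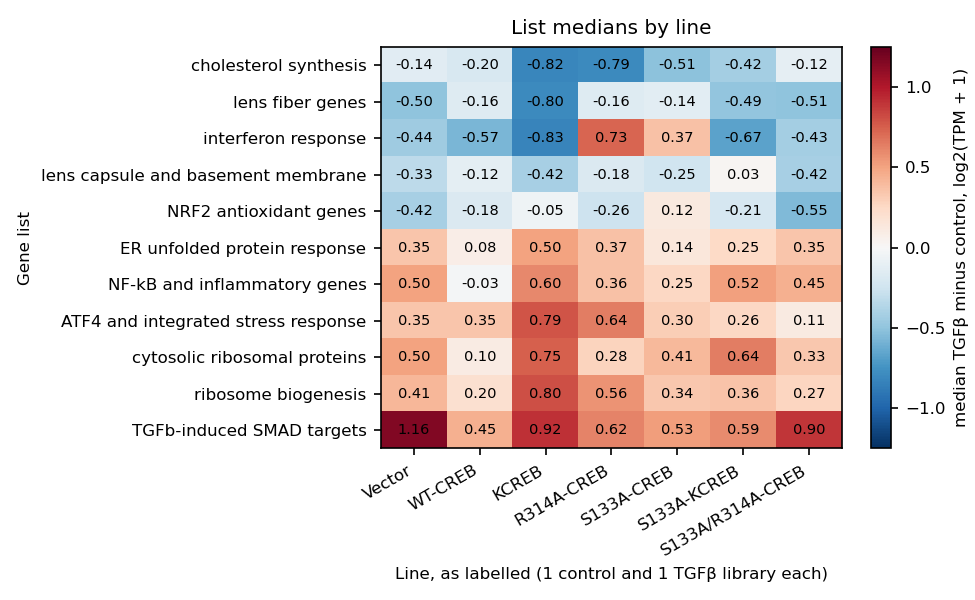
Median TGFβ minus control difference in log2(TPM + 1) of the 11 gene lists that passed camera at the preset correlation (vertical axis), in each of the 7 lines as labelled (horizontal axis), 1 control and 1 TGFβ library per line. SMAD targets are positive in all 7 lines, from 0.45 to 1.16, and the interferon list is positive in the lines labelled R314A-CREB and S133A-CREB alone.

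Genes of the mesenchyme and its matrix moved both ways, with 14 of 30 up and 8 down, or 15 and 9 adjusted over the list alone, and the list did not pass (adjusted p = 0.309). Fn1, or fibronectin, rose from 325 ± 371 to 1008 ± 596 TPM (log2 2.03 ± 0.23), Itga5 by 0.84 ± 0.09 and Col5a2 by 0.66 ± 0.06, whereas Timp3 changed by -0.90 ± 0.08. Of 3 members singled out after their values were seen, Col1a1 rose by 1.78 ± 0.28, smooth muscle actin (Acta2) fell in all 7 lines, from 1015 ± 368 to 485 ± 167 TPM, and vimentin (Vim) fell from 7815 ± 2270 to 5432 ± 1235 TPM. Lens epithelial regulators had 4 of 16 up and 8 down, or 4 and 9 adjusted over the list alone (adjusted p = 0.116), with Sox2 at -1.14 ± 0.09, Meis2 at -0.64 ± 0.08 and the Notch ligand Jag1 at 1.45 ± 0.17. Of the 7 EMT transcription factors tested, 3 rose and 2 fell in either count (adjusted p = 0.956), with Snai2 at 0.53 ± 0.11, Prrx1 at -1.06 ± 0.11 and Twist1 at -0.40 ± 0.06. Their median, 0.09, and their mean, -0.06, differ in sign. Epithelial junction and keratin genes had 3 of 8 down, among them Tjp1 (-0.35 ± 0.05), and none up in either count (adjusted p = 0.240). BMP and ID targets had 2 of 9 up and none down, or 1 adjusted over the list alone (adjusted p = 0.799). Integrins and focal adhesion genes had 5 of 21 up and 7 down, or 6 and 7 adjusted over the list alone (adjusted p = 0.799), with Itgb3 at 1.12 ± 0.13 and Itgb8 at -1.39 ± 0.13. YAP-TEAD targets had 2 of 16 up and 9 down, or 3 and 9 adjusted over the list alone (adjusted p = 0.146).

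The CREB-related lists did not pass. cAMP-CREB target genes had 7 of 29 up and 7 down in either count (adjusted p = 0.961), with Nfil3 at 1.29 ± 0.10 and Gadd45b at 0.79 ± 0.06. The CREB family and its coactivators had 4 of 13 up and 1 down in either count (adjusted p = 0.331), including Creb3l2 at 0.97 ± 0.11. Serum and immediate early genes had 11 of 27 up and 7 down, or 12 and 7 adjusted over the list alone (adjusted p = 0.512), with Myc at 1.07 ± 0.13 and Jun at 0.81 ± 0.11. G2-M cell cycle genes had 3 of 28 up and 2 down, or 3 and 1 adjusted over the list alone (adjusted p = 0.726). DNA replication genes had 12 of 28 up and 2 down in either count (adjusted p = 0.0917), including Fen1 at 0.28 ± 0.04. The p53 targets had 2 of 24 up and 3 down in either count (adjusted p = 0.320). Cytosolic heat shock genes had 5 of 13 up and 1 down, or 6 and 1 adjusted over the list alone (adjusted p = 0.331). Glycolysis and hypoxia genes had 3 of 21 up and 8 down, or 4 and 8 adjusted over the list alone (adjusted p = 0.328), with Vegfa at 0.64 ± 0.07. Oxidative phosphorylation genes had 2 of 31 up and 6 down, or 1 and 2 adjusted over the list alone (adjusted p = 0.0991).

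Markers of other cell types were tested where they reached a mean of 1 TPM. Of the macrophage markers 5 of 13 were tested, with 4 up and 1 down in either count (adjusted p = 0.320), Lyz2 at -1.37 ± 0.14. Of the muscle markers 5 of 14 were tested, with 3 up and 1 down in either count (adjusted p = 0.308), and cardiac troponin T (Tnnt2) rose from 55.6 ± 32.0 to 150 ± 44.6 TPM. The other lists had too few genes for a test. Of 16 crystallin genes, 3 were tested. Cryab fell from 908 ± 507 to 399 ± 99.7 TPM, Crygs was listed at 0 in all 7 TGFβ libraries and averaged 2.11 TPM in control, and Cryaa differed by 0.22 ± 0.20 (adjusted p = 0.400). Of 15 surface ectoderm and corneal markers, 4 were tested, and among these Aldh3a1 fell from 1163 ± 662 to 322 ± 297 TPM while Krt14 rose by 1.46 ± 0.35. The neuronal and retinal list had 1 gene of 16, Tubb3, which rose by 1.67 ± 0.38. The endothelial list had 1 of 12, Esam, at 1.34 ± 0.69 and 1.92 ± 0.73 TPM. Of 11 pigment epithelium and melanocyte markers 2 were tested, and Mitf rose by 0.46 ± 0.13.

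The next comparison set the 3 lines labelled S133A against the 3 labelled for the same constructs without it, each line as the mean of its 2 libraries and with the zipper state as a term. Cox7b2, a testis form of a cytochrome oxidase subunit, was higher by 3.81 ± 0.22 (log2, SE), with 37.8 to 61.1 TPM in the lines labelled S133A and 1.17 to 3.92 TPM in the CREB lines labelled without it. Nlrp4e, an oocyte NLR family gene, was higher by 3.80 ± 0.23, Pnma5 by 3.31 ± 0.54, Nlrp4f by 3.14 ± 0.23 and the immune receptor gene Cd48 by 2.94 ± 0.50. The Vector libraries also held Cox7b2, at 31.9 and 27.0 TPM, and Nlrp4f, at 10.4 and 10.6 TPM. On the lower side were Rsph9 (-1.81 ± 0.33), Neat1 (-1.50 ± 0.43), Ms4a4d (-1.50 ± 0.59), Nol3 (-1.43 ± 0.47) and Rgs16 (-1.41 ± 0.22). None of these passed. limma called 0 of 12,927 genes, with 753 at an unadjusted p under 0.05 and the smallest adjusted p at 0.0817, for Cox7b2 and Nlrp4e. Without the zipper term 4 genes passed, and 28 with all 12 libraries and the line as a random block, Cox7b2, Nlrp4e and Nlrp4f in both. The former fit does not match lines by zipper state. The latter uses 1 correlation (0.652) for all genes, so p-values are too small for genes whose 2 libraries of a line are more alike.

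Among the lists, none of whose members passed over all genes, 4 ranked apart for S133A. Cholesterol synthesis ranked lower (median -0.27, adjusted p = 5.27e-06; adjusted p = 0.868 with an estimated correlation), with Pmvk at -0.75 ± 0.17 and Fdps at -0.61 ± 0.16. SMAD targets ranked higher (median 0.26, adjusted p = 0.00134; adjusted p = 0.868 with an estimated correlation), with Nedd9 at 0.63 ± 0.16 and Cited2 at 0.64 ± 0.18. This call was lost without the line labelled KCREB (0.397) or S133A-KCREB (0.396). Ribosomal protein genes ranked lower (median -0.11, adjusted p = 0.00622; adjusted p = 0.868 with an estimated correlation), a call lost without the line labelled WT-CREB (0.644) or S133A-CREB (0.624). Integrins and focal adhesion genes ranked higher (median 0.26, adjusted p = 0.0347; adjusted p = 0.868 with an estimated correlation), with Itgb5 at 0.58 ± 0.14 and Pxn at 0.49 ± 0.14. That call was lost with no filter on low values (0.225) and without the line labelled WT-CREB (0.104), KCREB (0.106), S133A-CREB (0.10) or S133A-KCREB (0.106). No member of these 4 lists passed adjusted over the list alone. With the zipper state as a term, leaving out either line of a pair takes the whole pair out of the S133A effect. The losses without WT-CREB and without S133A-CREB thus rest on the same remaining pairs, as do those without KCREB and without S133A-KCREB.

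The lines labelled with K were compared with those labelled WT-CREB and S133A-CREB. These groups also differed in Creb1, as given above, against the labels of the latter, so the values are not read as an effect of lost DNA binding. Inhbb, an activin subunit gene (chromosome 1, 119343193 to 119349978), was lower by 4.81 on the log2 scale (-4.81 ± 0.27, adjusted p = 0.118). It had 0.240 to 1.67 TPM in the lines labelled with K and 34.5 to 71.9 TPM in those labelled WT-CREB and S133A-CREB. The interferon-induced gene Ifitm3 differed by -5.85 ± 0.68, from 239 to 893 TPM in these 2 lines against 2.35 to 23.7 TPM, followed by Ms4a4d (-5.28 ± 0.73), Xlr (-4.92 ± 0.69) and the glypican Gpc1 (-4.34 ± 0.62). On the higher side were Fez1 (4.40 ± 1.25), Khdrbs3 (3.81 ± 1.63), Arhgdib (3.18 ± 1.17), Usp17la (3.01 ± 0.55) and Wnt7a (3.0 ± 0.52). The matched pairs disagreed in size for Fez1 (1.43 to 7.78) and Arhgdib (0.483 to 5.54). Khdrbs3 was at 0 and 0.0486 TPM in the line labelled WT-CREB alone, and at 62.7 TPM or more in all other libraries. limma called 0 genes, with 1310 at an unadjusted p under 0.05. Fits without 1 line called 16 genes without the line labelled WT-CREB and 19 without S133A-CREB, among them Inhbb in both.

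For K, 6 lists ranked apart, again with no member called over all genes. Mesenchymal and matrix genes ranked lower (median -0.85, adjusted p = 1.05e-04; adjusted p = 0.994 with an estimated correlation), with Col6a2 at -4.10 ± 0.42, Fn1 at -2.27 ± 0.22 and Col6a1 at -2.10 ± 0.32, and 6 of 30 were lower adjusted over the list alone. NF-kB and inflammatory genes ranked lower (median -0.91, adjusted p = 3.06e-05; adjusted p = 0.994 with an estimated correlation), and 7 of 15 were lower adjusted over the list alone, including Tnfrsf9 (-2.82 ± 0.31), Vcam1 (-2.79 ± 0.54) and Lif (-1.96 ± 0.28). G2-M genes ranked higher (median 0.27, adjusted p = 6.31e-06; adjusted p = 0.994 with an estimated correlation), with Mki67 at 0.61 ± 0.16, a call lost without the line labelled S133A-KCREB (0.0516). The unfolded protein response ranked higher (median 0.35, adjusted p = 3.6e-05; adjusted p = 0.994 with an estimated correlation), with Xbp1 at 0.80 ± 0.18, a call lost without the line labelled KCREB (0.294). Lens epithelial regulators ranked higher (median 0.55, adjusted p = 0.0150; adjusted p = 0.994 with an estimated correlation), and 4 of 16 were higher and 2 lower adjusted over the list alone. They include Tfap2a (1.46 ± 0.33), Jag1 (1.39 ± 0.26) and Gata3 (-1.31 ± 0.29). This call was lost with no filter on low values (0.0560) and without the line labelled WT-CREB (0.130) or KCREB (0.194). Interferon response genes ranked lower (median -1.01, adjusted p = 0.00300; adjusted p = 0.994 with an estimated correlation), with Cxcl10 at -3.22 ± 0.80. Their median turned to 0.64 without the line labelled S133A-CREB, and the call was lost without S133A-KCREB (0.706) and with no filter on low values (0.0648).

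The R314A comparison used the same 2 lines, labelled WT-CREB and S133A-CREB, as the K comparison, so resemblance between the 2 is partly built in. Creb1 lay below Vector in all 4 of its lines. Col6a2, a collagen VI chain, differed by -4.10 ± 0.42 (adjusted p = 0.552), from 36.9 to 143 TPM in these 2 lines against 1.25 to 14.4 TPM in the lines labelled R314A. The other named genes were Ms4a4d (-4.58 ± 0.73), Magea13 (-3.68 ± 1.84), Adh7 (-3.65 ± 0.66) and Rhox5 (-3.63 ± 1.49) on the lower side. On the higher side were Vmn2r79 (3.73 ± 0.47), Efemp1 (3.61 ± 2.13), Khdrbs3 (3.43 ± 1.63), the membrane endopeptidase gene Mme (3.15 ± 0.66) and Lncenc1 (3.05 ± 0.55). The matched pairs disagreed in size for 2 of these, from 1.37 to 7.17 for Efemp1 and from 0.0437 to 6.77 for Khdrbs3. Magea13 stood at 166 and 180 TPM in the line labelled S133A-CREB and at 0.364 TPM or less in all other libraries, so that 1 line sets its value. limma called 0 genes, with 821 at an unadjusted p under 0.05. The fit without the line labelled S133A-CREB called 21.

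For R314A, 7 lists ranked apart. NF-kB and inflammatory genes ranked lower (median -0.59, adjusted p = 1.19e-05; adjusted p = 0.705 with an estimated correlation), with Vcam1 at -2.37 ± 0.54 and Il6 at -1.28 ± 0.24, and 3 of 15 were lower adjusted over the list alone. Mesenchymal and matrix genes ranked lower (median -0.62, adjusted p = 0.00486; adjusted p = 0.705 with an estimated correlation), with Col6a1 at -2.25 ± 0.32 and Fn1 at -1.25 ± 0.22, and 4 of 30 were lower adjusted over the list alone. G2-M genes ranked higher (median 0.25, adjusted p = 9.94e-05; adjusted p = 0.705 with an estimated correlation), a call lost without the line labelled S133A-CREB (0.0527). The unfolded protein response ranked higher (median 0.25, adjusted p = 0.00573; adjusted p = 0.705 with an estimated correlation), with Edem1 at 0.52 ± 0.16. It was lost with quantile normalization (0.0606) and without the line labelled WT-CREB (0.226) or S133A/R314A-CREB (0.370). Cytosolic heat shock genes ranked higher (median 0.21, adjusted p = 0.0276; adjusted p = 0.705 with an estimated correlation), and were lost with quantile normalization (0.0785) and without WT-CREB (0.204) or S133A/R314A-CREB (0.0726). Cholesterol synthesis ranked lower (median -0.16, adjusted p = 0.0130; adjusted p = 0.705 with an estimated correlation), with Stard4 at -0.68 ± 0.17, and was lost without WT-CREB (0.456) or R314A-CREB (0.567). Oxidative phosphorylation ranked higher (median 0.07, adjusted p = 0.0309; adjusted p = 0.705 with an estimated correlation), and was lost with quantile normalization (0.235) and without S133A-CREB (0.790) or S133A/R314A-CREB (0.626).

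Interactions tested whether the TGFβ response itself differs between lines. For S133A, Mmp9 had the largest positive value, 2.19 ± 0.29 (log2, SE, adjusted p = 0.828). It went from 10.4 to 268, from 3.96 to 60.0 and from 21.2 to 109 TPM in the lines labelled S133A/R314A-CREB, S133A-KCREB and S133A-CREB, and from 2.51 to 5.90, 3.67 to 8.29 and 3.27 to 15.5 TPM in the lines labelled WT-CREB, KCREB and R314A-CREB. Krt14 (1.77 ± 0.46), Cd40 (1.47 ± 0.34), Cnbd2 (1.25 ± 0.22) and Glipr1 (1.21 ± 0.30) followed. Lowest were the neighbouring mitochondrial tRNA genes TrnH (-1.56 ± 0.22), TrnS2 (-1.52 ± 0.18) and TrnL2 (-1.44 ± 0.17), then Dhrs3 and Eda2r. limma called 0 genes, with 455 at an unadjusted p under 0.05. Of the 3 lists that ranked apart, the ATF4 and integrated stress response ranked lower (median -0.33, adjusted p = 1.41e-09; adjusted p = 0.917 with an estimated correlation), including Atf5 (-0.62 ± 0.11), Chac1 (-0.57 ± 0.16) and Slc7a5 (-0.42 ± 0.10). Only Atf5 was lower adjusted over the list alone.

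For K and TGFβ, limma called 0 genes, with 1392 at an unadjusted p under 0.05 and a smallest adjusted p of 0.263. The collagen gene Col3a1 had the highest value, 2.75 ± 0.39. It went from 7.55 to 44.0 and from 23.2 to 38.8 TPM in the lines labelled KCREB and S133A-KCREB, and from 87.5 to 39.3 and from 431 to 179 TPM in the lines labelled WT-CREB and S133A-CREB. Asb5 (2.74 ± 0.26), Tgfbi (2.62 ± 0.51), the tenascin gene Tnc (2.57 ± 0.27) and Tubb3 (2.49 ± 0.45) followed. Lowest were Slurp1 (-3.59 ± 0.42), Mir703 (-2.44 ± 0.34), Fgfr3 (-2.01 ± 0.59), Ndufs5 (-1.86 ± 0.27) and Prelp (-1.86 ± 0.22). The pair differences of Fgfr3 were unequal, at -3.35 and -0.665. Without either line labelled R314A-CREB or S133A/R314A-CREB, 15 genes passed. For R314A and TGFβ, limma called 0 genes with 829 at an unadjusted p under 0.05, and 1 without the line labelled S133A/R314A-CREB. Clu (2.43 ± 1.11), Rgs16 (2.27 ± 0.33), Tnc (2.09 ± 0.27), Mir7026 (1.97 ± 0.33) and Tubb3 (1.79 ± 0.45) were highest and Slurp1 (-2.92 ± 0.42), the glutathione transferase Gsta2 (-2.71 ± 0.36), Shroom2 (-2.46 ± 0.28), the quinone reductase Nqo1 (-1.96 ± 0.25) and Efemp1 (-1.89 ± 0.85) lowest. The value for Clu came from the line labelled S133A/R314A-CREB alone, with pair differences of 4.76 there and 0.10 for the line labelled R314A-CREB. For Efemp1 the pair differences were -3.21 and -0.574. The larger is against the line labelled S133A-CREB, where Efemp1 was at 0.295 and 0 TPM. Nqo1 went from 128 to 36.3 and from 166 to 43.6 TPM in the lines labelled R314A, and from 87.8 to 79.5 and from 52.2 to 67.4 TPM in the lines labelled WT-CREB and S133A-CREB. At the preset correlation 10 lists ranked apart for K and 11 for R314A, and 0 with an estimated correlation.

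Taken singly, the lines differed in how many of 10,530 genes with a mean of at least 5 TPM moved past 2-fold with TGFβ. These counts describe 1 library against 1 library and have no replicate check. The line labelled KCREB had 693 (316 higher, 377 lower), Vector 512, S133A/R314A-CREB 448, R314A-CREB 408, S133A-KCREB 404, S133A-CREB 223 and WT-CREB 119 (48 higher, 71 lower). Tgfbi went from 1.40 to 47.0 TPM in Vector and from 11.6 to 21.5 TPM in the line labelled WT-CREB, and Prelp from 381 to 50.4 and from 120 to 55.1 TPM. Across genes, the responses of pairs of lines correlated with r from 0.498 to 0.843 (median 0.669, 21 pairs, Pearson; genes are not independent replicates, and no pair shares a library).

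Against the single Vector library of each treatment, the line labelled WT-CREB differed past 2-fold at 1073 genes in control and 773 with TGFβ, S133A-CREB at 765 and 689, S133A-KCREB at 625 and 560, S133A/R314A-CREB at 522 and 433, R314A-CREB at 367 and 387 and KCREB at 288 and 279, again with no replicate check. In the line labelled WT-CREB, Gpc1 stood at 183 and 245 TPM against 0.830 and 1.47 in Vector, the basement membrane collagen Col4a1 at 93.7 and 85.1 against 0.0768 and 0.0652, and Aif1l at 55.9 and 75.1 against 0.133 and 0. Bex1 was at 0 and 0.134 TPM against 420 and 142 in Vector. Scarf2 was among the 3 highest differences in the other 5 lines, with 22.6 to 65.3 TPM against 0.0179 and 0.0893 in Vector. Fmr1nb was among the 3 lowest in those 5 lines, at 0.196 TPM or less against 74.2 and 53.8. Mme was among the 3 lowest in all lines but the one labelled R314A-CREB, with 110 and 66.4 TPM in Vector. Other named genes that were higher than in Vector were Snx15 and Aif1l (KCREB), Col1a2 and Gatm (R314A-CREB), Magea13 and Asb5 (S133A-CREB), Gatm and Aif1l (S133A-KCREB) and Ripk3 and Septin3 (S133A/R314A-CREB). Lower were Khdrbs3 (WT-CREB), Xlr (KCREB), Ptprtos and Cyp3a41a (R314A-CREB), Efemp1 (S133A-CREB), Mmp2 (S133A-KCREB) and Zfp13 (S133A/R314A-CREB).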

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

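The refits of lists without each line in turn and with no filter were chosen after the list results were seen, and the other tests of this part before. Dixon's test at the 95% level was applied to 52 sets of 7 lines or libraries, and chance marks about 1 set in 20. It marked 1. The TGFβ difference of Clu was 7.17 (log2) in the line labelled S133A/R314A-CREB and 1.74 to 3.65 in the other 6 lines, a gap of 0.649 of the range.

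Differences in the TGFβ response between groups of lines were seen in 24 list tests at the preset correlation. No single gene passed in these interactions, and no list passed with an estimated correlation (adjusted p = 0.917 for S133A, 0.781 for K and 0.895 for R314A with an estimated correlation). For S133A, the response of the ATF4 and integrated stress response list was lower (adjusted p = 1.41e-09), with line medians of 0.79, 0.64 and 0.35 in the lines labelled KCREB, R314A-CREB and WT-CREB and 0.11, 0.26 and 0.30 in those labelled S133A/R314A-CREB, S133A-KCREB and S133A-CREB. Cholesterol synthesis was higher (median 0.23, adjusted p = 5.61e-05) and ribosome biogenesis lower (-0.19, adjusted p = 0.00132). Only the ATF4 list passed without each line in turn.

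For K, none of the 10 calls held with an estimated correlation (adjusted p = 0.781). At the preset one the response was higher in cytosolic ribosomal proteins (median 0.45, adjusted p = 1.53e-08), NF-kB and inflammatory genes (0.71, adjusted p = 3.26e-04), ribosome biogenesis (0.32, adjusted p = 3.1e-04), the unfolded protein response (0.25, adjusted p = 0.00223) and SMAD targets (0.33, adjusted p = 0.00844). It was lower in oxidative phosphorylation (-0.18, adjusted p = 1.28e-05), interferon response (-0.68, adjusted p = 2.09e-05), lens fiber genes (-0.56, adjusted p = 5.83e-04), cholesterol synthesis (-0.30, adjusted p = 6.05e-04) and NRF2 antioxidant genes (-0.13, adjusted p = 7.82e-04). Of these 10, lens fiber genes, NF-kB, ribosomal proteins and oxidative phosphorylation passed without each line in turn and 6 lost the call or turned. With no filter on low values the lens fiber call was lost (median -0.0632, adjusted p = 0.0867). Nfkbia (0.77 ± 0.12, SE) and Ptgs2 (1.23 ± 0.26) led the NF-kB list, and Ndufb3 (-0.67 ± 0.12) the oxidative phosphorylation list.

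For R314A, likewise none of the 11 calls held with an estimated correlation (adjusted p = 0.895). At the preset one the response was lower in NRF2 antioxidant genes (median -0.37, adjusted p = 2.82e-08), p53 targets (-0.27, adjusted p = 0.0269), lens capsule genes (-0.17, adjusted p = 0.0269), oxidative phosphorylation (-0.08, adjusted p = 0.0269) and lens fiber genes (-0.22, adjusted p = 0.0395). It was higher in the unfolded protein response (0.24, adjusted p = 3.03e-04), NF-kB and inflammatory genes (0.27, adjusted p = 0.00110), ribosome biogenesis (0.15, adjusted p = 0.0144), mesenchymal and matrix genes (0.12, adjusted p = 0.0269), cAMP-CREB targets (0.09, adjusted p = 0.0269) and SMAD targets (0.27, adjusted p = 0.0269). All 11 of these calls were lost or turned without at least 1 line. Nqo1 (-1.96 ± 0.25, SE) and Gstm1 (-1.10 ± 0.16) led the NRF2 list and Nfil3 (0.67 ± 0.13) and Atf3 (1.34 ± 0.30) the cAMP-CREB list. K and R314A were compared with the same 2 lines, labelled WT-CREB and S133A-CREB, whose TGFβ responses were the smallest of the 7.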

How the results depend on the processing

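The tests chosen after the result was seen are the rescaling without mitochondrial genes, the 3-line fit and the list tests outside median-of-ratios scaling and the estimated correlation. The TGFβ effect called between 4038 genes (lines labelled Vector, KCREB and S133A-KCREB alone) and 5918 (without WT-CREB), except without the replicate block. There the pairing by line was dropped and 1164 genes passed, all of them among the 5872. The 20 named genes kept direction and call in every alternative, save Asb5 and Efemp1 in that fit. The Wilcoxon test could not have lost them, since the rule that named them asked for one direction in all 7 lines, which gives its smallest p. The effects of S133A, K and R314A and their interactions stayed at 0 genes, with exceptions. Without the bzip term, S133A had 4, and 28 with 12 libraries and the line as a random block (27 higher, 1 lower; estimated correlation 0.652). Leaving out 1 line gave 0 to 19 genes for K, 0 to 21 for R314A, 0 to 15 for K by TGFβ and 0 to 1 for R314A by TGFβ. Such fits have fewer lines, and a line left alone in its zipper state is fitted exactly by the term of that state. In K and R314A estimates that use the lone line, it is assumed to vary like the others. For S133A and its interaction it adds nothing, so leaving out either line of a pair leaves the same pairs to compare. For K and its interaction, leaving out either line labelled R314A likewise leaves the same comparison. With an estimated correlation, 0 lists passed in each of the 7 effects. That test has few residual degrees of freedom and its power was not measured. These failures thus neither uphold the lists nor show that they do not differ.

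The number of lists called ran, without 1 line, from 5 to 7 for S133A (4 with all lines), 6 to 11 for K (6), 6 to 12 for R314A (7), 3 to 11 for S133A by TGFβ (3) and 5 to 14 for R314A by TGFβ (11). Quantile normalization gave 4 for R314A. For S133A by TGFβ, a pseudocount of 5 gave 5 and a filter at 5 TPM gave 6. No filter on low values gave 5 for R314A by TGFβ. Leaving out 1 line turned the direction of 5 called lists in camera. The median ran from -2.69 to 0.64 for interferon response under K, from -0.69 to 0.10 for cholesterol synthesis under K by TGFβ and, under R314A by TGFβ, from -0.13 to 0.41 for ribosome biogenesis. For mesenchymal genes (0.00926 to 0.48) and p53 targets (-0.33 to -0.0173) it came near 0 but kept its sign. The cause was not tested.

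Lowering the filter from 5 to 1 TPM, which adds genes, raised some counts past 2-fold. With TGFβ they were 774 in Vector, 213 in WT-CREB, 638 in R314A-CREB and 386 in S133A-CREB. Against Vector (control, TGFβ) they were 522 and 518 for KCREB, 647 and 656 for R314A-CREB, 1192 and 1076 for S133A-CREB, 975 and 874 for S133A-KCREB, 829 and 730 for S133A/R314A-CREB, and 1195 with TGFβ for WT-CREB. Single named genes, single called lists and Creb1 levels were compared with each alternative. Of these comparisons, 2072 were unchanged, 139 lost a call, 27 gained one and 6 turned. Unchanged means the same direction and side of the threshold, or for Creb1 a shift under 1 SD over libraries. The 6 are the turned lists given above. Named genes outside the TGFβ effect had not passed in the main fit, so for them unchanged means that they again did not pass. Read totals are unknown, so the limit that depth sets on low genes could not be given.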

Other observations

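All tests in this part were chosen after the result they bear on was seen, except the 7-gene test of removal by gene name. Against Vector, lists whose median lay at or beyond the 0.1 or 99.9 percentile of matched random lists in both treatments describe each line, with 1 library per side and no test. NF-kB and inflammatory genes were higher in the lines labelled WT-CREB (median log2 1.40 in control and 0.77 with TGFβ), S133A-CREB (1.16 and 1.11), S133A-KCREB (0.50 and 0.63), S133A/R314A-CREB (0.49 and 0.58) and R314A-CREB (0.48 and 0.56), and -0.15 and 0.17 in the line labelled KCREB. Mesenchymal and matrix genes were higher in the lines labelled S133A-CREB (1.30 and 0.72), WT-CREB (0.66 and 0.29) and S133A/R314A-CREB (0.29 and 0.32). The unfolded protein response was lower in the lines labelled WT-CREB (-0.43 and -0.63) and R314A-CREB (-0.40 and -0.27). Lens epithelial regulators were lower in the line labelled WT-CREB (-1.04 and -0.84). The interferon list was higher in the lines labelled S133A-CREB (0.96 and 1.98) and R314A-CREB (0.24 and 1.69) and lower in those labelled S133A-KCREB (-0.77 and -0.98) and WT-CREB (-0.41 and -0.74). Cholesterol synthesis was lower in the lines labelled S133A-CREB (-0.46 and -0.77), S133A-KCREB (-0.45 and -0.81) and S133A/R314A-CREB (-0.66 and -0.75). Muscle markers were lower in the lines labelled KCREB (-1.94 and -1.16) and S133A/R314A-CREB (-0.96 and -1.50), and p53 targets in KCREB (-0.47 and -0.39). The line labelled S133A-KCREB had higher SMAD targets (0.59 and 0.27) and serum and immediate early genes (0.32 and 0.52), and lower NRF2 (-0.56 and -0.41) and ATF4 genes (-0.33 and -0.42).

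Of the genes named for large differences between lines, 4 X-linked examples, chosen after their values were seen from a larger number (others are Bex1 and Pnma5), are given here, and whether X-linked or germ-line genes vary more than others was not tested. The homeobox gene Rhox5 stood at 678 and 667 TPM in the line labelled WT-CREB, 425 and 409 in S133A-CREB, 336 and 245 in S133A-KCREB and 106 and 97.4 in S133A/R314A-CREB, against 13.5 and 16.7 in Vector, 16.6 and 17.2 in R314A-CREB and 3.98 and 3.11 in KCREB. Xlr stood at 161 and 144 TPM in the line labelled S133A-CREB, above Vector (103 and 106), and at 0 and 0.991 in KCREB. Magea13 was at 166 and 180 TPM in S133A-CREB and at 0.364 TPM or less elsewhere, and Fmr1nb was at 74.2 and 53.8 TPM in Vector and at 0.196 TPM or less in all CREB lines but WT-CREB. Among other named genes, Khdrbs3 was near 0 in the line labelled WT-CREB alone and Efemp1 was at 0.295 TPM or less in S133A-CREB. With 1 line per construct, a difference between founder cells and an effect of the construct cannot be separated for these genes, and neither was tested.

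Cytosolic ribosomal protein genes, usually among the most abundant mRNAs, had a median of 16.0 TPM and 0.130% to 0.249% of TPM in each library. Low expression of translation genes argues poorly here, since 21 translation factors stood 26.2 times higher, and Fau, which encodes a ribosomal protein under another name, was at 1304 TPM. Loss of reads shared with pseudogenes is countered by the mitochondrial ribosomal protein genes, which have few such copies and were also low, with proteasome subunits 94.8 times higher. Removal before deposit of genes by the words ribosomal protein was to be tested on 7 genes (median 1.50 TPM), but 4 of them are among the 82 to be explained and the other 3 (4.43 TPM) are too few. In a wider test set after the values were seen, these 3 and 10 ribosomal protein S6 kinases had a median of 1.66 TPM. All 13 lay below the lower quartile of tested genes (8.63 TPM). The 5 mitochondrial ribosome subunits without the name (30.6 to 99.6 TPM) had a median of 88.9 TPM against 2.47 TPM in the 78 with it. Removal by name would give these values. However, genes named for ribosomal RNA processing were also low, from 1.17 TPM (Rrp1b) to 8.34 TPM (Rrp1). Nop56, Nop58, Fbl and Ncl had 137 to 293 TPM. Low levels thus reach genes without the words ribosomal protein, and removal by these words alone does not account for them. Removal by a wider match of names, such as the word ribosomal alone, was not tested and is not excluded. No biological explanation by group was tested.

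Creb1 lay below Vector in 4 lines labelled for a CREB construct. Scaling is excluded, since the highest of the 4 lines stayed at 0.560 times the lower Vector library after median-of-ratios scaling, and an exchange of single libraries is excluded by the correlation of the 2 libraries of a line, 0.614 at the lowest. Construct reads not counted under mouse Creb1 would by themselves leave the cells' own Creb1 at the Vector level. The mean log2 ratio of the 4 lines to Vector was -1.58 (SD 0.40 between them). These lines were picked for Creb1 below Vector, however, which fixed the sign. With 1 Vector line the spread of the cells' own Creb1 between lines is unknown, so this test cannot decide and uncounted construct reads stay open. An exchange of whole lines, with 2 lines at or above Vector, also stays open, because no value used here identifies a line apart from Creb1 itself. A biological hypothesis is that endogenous Creb1 is lowered where the construct still binds DNA. The lines labelled with K were higher than the other 4 CREB lines by 1.97 (log2), with an exact two-sided permutation p of 0.0667, the smallest that 15 splits allow, so this stays open.

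The line labelled WT-CREB had the smallest TGFβ differences, with a slope of 0.444 on the mean of the other lines, where a control and a TGFβ library exchanged would give a negative one. Depth is argued against by a slope of 1.25 in a line with a shallower library. Its control library may already be shifted along the TGFβ response. The difference of its control library from other controls correlated across genes with the TGFβ response of lines not used for that difference, with a mean r of 0.311 (0.223 to 0.363 over 20 ways), against means of -0.329 to 0.139 in the other 6 lines. This control library had the highest share of TPM in mitochondrially encoded genes (10.8%) and in the top 10 genes (13.4%) of the 14 libraries. The TGFβ library of the same line came next on both, at 8.64% and 11.6%, so high shares are not particular to the control. With TGFβ the mitochondrial share was lower in every line but the one labelled S133A/R314A-CREB (5.59% to 6.04%). A high share thus does not point to a shift toward the TGFβ state. The correlation does not tell a shifted control culture from a lasting difference of this line from the others. Whether the construct or the state of the culture played a part was not tested.

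Other splits of the same samples were counted for 3 fits. For TGFβ, of 64 ways to exchange control and TGFβ within lines, 1, the real one, reached 5872 genes, and the highest other called 2468 (with the line labelled WT-CREB exchanged). The 10 splits of the 6 CREB lines into 3 and 3 are too few for a share under 0.05. For S133A the real split called 0 genes and the highest other 10, and for S133A by TGFβ the real split and the highest other both called 0.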
